A study of Mus musculus with 2 samples.

How the data were processed

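Long-read RNA sequencing of whole molecules was carried out on adrenal glands of male mice aged 2 months of the strain B6CASTF1/J, an F1 hybrid that carries a B6 and a CAST genome. The 2 libraries form a single group, so no contrast between groups exists, and replicate numbers were taken from the labels. The biosample labels number the animals 3 and 4, whereas the library descriptions give the number 3 for both, so the libraries are not shown to come from separate animals. Spread between them may therefore be technical, and any test between them compares these libraries only.

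The authors deposited counts of reads per transcript model, as whole numbers with no normalization, in 1 table per library. Per the deposited notes, the reads were aligned to the mouse build mm10 and annotated against GENCODE M21 with spike-in sequences. The aligner, the sequencing platform and the software versions are not given in the sources used here. Transcript models were written by TALON, per the source field of the deposited annotation, which also gives the exon coordinates used here. The other deposited columns hold the number of exons and the length of each model, which for an annotated model is its annotated length. TALON classes were used as deposited: annotated (Known), incomplete splice match (ISM), new combination of known splice sites (NIC), new splice site (NNC), no compatible splice pattern (genomic), antisense and intergenic. Each library had been processed on its own, so new spliced models were matched by chromosome, strand and intron chain, and new loci by overlap on the same strand. How strand was set is not given in the sources used here.

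Reads were summed per annotated gene over every class, and reads on ERCC spike-ins were taken out of the totals. This left 824225 reads in replicate 1 and 656826 in replicate 2, with 5731 spike-in reads (0.691%) and 5156 (0.779%). The labels also name a second spike-in set (SIRV), which is not used here. Levels are CPM of gene-assigned reads, as mean ± SD over n = 2. A count of 0 allows up to 3 reads, or 3.64 CPM in replicate 1 and 4.57 CPM in replicate 2. Shares of reads per library carry Wilson 95% intervals. These intervals and floors cover counting error only, since the reads carry no molecular identifiers in the files used here.

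Log2 ratios are replicate 2 over replicate 1 on TMM-scaled CPM with 1 CPM added (edgeR 4.0.16, R 4.3.3). Scaling by TMM instead of by the total moves the log2 ratio of all genes by 0.10. The quasi-likelihood test of edgeR needs groups with replicates and could not be fitted. Each gene with at least 20 reads in sum was instead given a two-sided exact binomial test of its reads in the libraries, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and at least a 2-fold ratio. Calls for fixed lists are given over all genes tested and adjusted over the list alone. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Counts over genes with at least 10 reads in sum were compared by chi-square, and the biological coefficient of variation came from edgeR's common dispersion. Dominant transcripts of genes with at least 20 reads in each library were compared by a two-sided Fisher's exact test, called at an adjusted p under 0.05 and a difference of at least 10 percentage points. A gene counted as having more than 1 major transcript where no transcript held 90% of its reads. New spliced transcripts and loci were counted with at least 5 reads in each library. Inclusion of an annotated internal exon is the share of reads that hold it among reads that hold or skip it, for exons with at least 20 such reads in each library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9.

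The lists, tests and the rule for named genes were fixed before the data were examined. The lists were steroidogenesis and cholesterol delivery, cholesterol synthesis, zona glomerulosa, zona fasciculata, X-zone, chromaffin cells, capsule and connective tissue, endothelium, macrophages and lymphocytes, erythroid cells, adipocytes, kidney, liver, Schwann cells and other glia, immediate early and heat shock genes, circadian clock, mitochondrially encoded genes, sex-linked genes, and an isoform list. The rule named the 15 genes of highest mean CPM, the 4 most abundant members of each list with a few fixed genes, and the 10 called genes of largest ratio in each direction. It also named the dominant transcript of each isoform-list gene with at least 50 reads in each library, the 10 most abundant new spliced transcripts, the 5 most abundant new loci and the 5 genes with the largest difference in transcript usage. Genes named outside this rule were chosen after their values were seen. Some items that the rule names are not reported here.

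The tests were also tried on counts simulated from the real genes and library sizes with sampling noise only. For the rates given here, neither spread beyond that noise nor a trend with transcript length was put in, though the real libraries held both. The rates therefore hold for such counts and do not carry over to the real libraries. Of genes changed 3-fold, 68% were called, 92% at 4-fold, 100% at 6-fold and 2.13% at 1.5-fold, while 0 of 7853 unchanged genes were called. Of 50 simulated lists with no shift 3 fell outside the central 95% of random lists, and 50 of 50 did so with a shift of 0.5. The usage test called 51% of genes moved by 30 points and 1 gene that was not moved. Alternatives changed the scaling (total, DESeq2 1.42.0 size factors), the read minimum, the pseudocount, the classes of reads counted, the depth by thinning, the thresholds for transcripts and the replicate used. Removal of the trend of the ratio with transcript length (running median over 40 bins) and restriction to genes that overlap no other gene were added after the data were seen. Genes with no reads on an annotated model had no length and were taken at the median length of the tested genes that had one. Spike-ins with at least 50 reads in sum were compared between length classes by a two-sided exact permutation test of their log2 ratios, and a rank correlation with length over all of them by a permutation test with 100000 resamples, also added then.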

Results

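Adrenal glands of male B6CASTF1/J mice aged 2 months were profiled by long-read RNA sequencing in 1 group of 2 libraries. The adrenal gland has a cortex, which makes steroid hormones in concentric zones, and a medulla of chromaffin cells, which make catecholamines. Replicate 1 held 824225 gene-assigned reads and replicate 2 held 656826, on 88716 and 85696 transcript models. Reads were found on 15067 annotated genes in replicate 1 and 14582 in replicate 2. Annotated genes took 97.1% and 97.2% of the reads. The labels give no treatment, so the values below describe the tissue and how far the libraries differ.

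Genes of steroid synthesis headed the transcriptome. Cyp11a1, the side-chain cleavage enzyme that opens steroid synthesis, was highest at 23120 ± 4575 CPM (mean ± SD, n = 2), followed by the 21-hydroxylase gene Cyp21a1 at 13534 ± 3384 CPM and Star, which moves cholesterol into mitochondria, at 13340 ± 1883 CPM. The 11β-hydroxylase gene Cyp11b1 stood at 8603 ± 1489 CPM and Hsd3b1 at 7623 ± 37.1 CPM. The fat-cell gene Car3 ranked 6 at 7081 ± 2226 CPM, ahead of the transporter gene Abcb1b (5063 ± 877 CPM), Srd5a2 (5053 ± 764 CPM), the actin-severing protein gene Gsn (4422 ± 773 CPM) and Akr1b7 (4258 ± 354 CPM). The granule protein genes Chgb (4220 ± 471 CPM) and Chga (3717 ± 401 CPM), the desaturase gene Fads2 (4134 ± 518 CPM), the potassium channel gene Kcnk3 (3446 ± 492 CPM) and the fat-cell gene Cfd (3432 ± 1138 CPM) completed the 15 most abundant genes. The 10 most abundant genes took 9.21 ± 0.0431% of the reads.

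The Cyp11a1 level depended on which reads were counted. Single-exon reads made up 50.3% of its reads in replicate 1 (10935 reads) and 28.3% in replicate 2 (3698 reads). Without reads of no compatible splice pattern, Cyp11a1 stood at 14241 ± 720 CPM, with a log2 ratio of 0.01 in place of -0.51. The gene (ENSMUSG00000032323.13) lies on chromosome 9 from 58006411 to 58028677 (mm10).

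The 23 genes for steroidogenesis and cholesterol delivery took 7.67 ± 0.256% of the reads, and 1 of the 23 was called between the libraries. At an adjusted p under 0.05 alone, 14 of the 23 differed between the libraries, among them Cyp11a1 (log2 ratio -0.51), Cyp21a1 (0.41), Apoe (-0.64) and Scarb1 (0.55), each of these under 2-fold. Cholesterol synthesis genes took 0.263 ± 0.0515%, led by Dhcr7 (647 ± 88.2 CPM), Insig1 (369 ± 131 CPM), Msmo1 (278 ± 71.2 CPM) and Hmgcs1 (212 ± 61.6 CPM). Of the 20 tested, 1 was called. Of these 20 genes 14 were higher in replicate 2, and their median log2 ratio of 0.24 stood at percentile 96.9 of matched random lists, inside the central 95%. At an adjusted p under 0.05 alone 4 differed, and 2 with the trend of the ratio with transcript length removed, a step chosen after seeing the data. Msmo1 (log2 ratio 0.43 and then 0.36) and Hmgcs1 (0.50 and then 0.34) no longer passed but kept their direction. The list median was then 0.22, at percentile 98.4. Each call compares these libraries only, and adjusted over the list alone the counts were again 1 and 1.

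Genes of the outer and middle cortex were both present. Cyp11b2, the aldosterone synthase of the zona glomerulosa, stood at 1656 ± 554 CPM, with Wnt4 at 282 ± 5.46 CPM, Hsd3b6 at 265 ± 10.8 CPM and Dab2 at 205 ± 43.3 CPM. The glomerulosa list took 0.269 ± 0.0640% of the reads and the fasciculata list 2.07 ± 0.278%, the latter led by Cyp11b1, Abcb1b, Akr1b7 and the lipoprotein receptor gene Scarb1 (2400 ± 753 CPM). None of the 8 glomerulosa and 6 fasciculata genes tested was called, with median log2 ratios of 0.25 (percentile 94.2) and 0.20 (percentile 96.1). At an adjusted p under 0.05 alone, 1 and 4 differed. With that trend removed, Cyp11b1 moved from 0.25 to 0.06, Abcb1b from 0.25 to 0.04 and Akr1b7 from -0.27 to 0.01, and these no longer passed. Scarb1 still did (0.55 and 0.48), and Mrap, the melanocortin receptor accessory protein gene, did so newly (0.16 and 0.65). Cyp17a1, the 17-hydroxylase that mice lack in the adult adrenal cortex, had 0 reads in replicate 1 and 3 in replicate 2. The X-zone, a fetal-type inner zone, left little trace: Akr1c18 had 1 and 0 reads and Thrb 6 and 4, while Pik3c2g had 0 in both, which allows up to 3.64 and 4.57 CPM.

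Chromaffin-cell genes took 1.58 ± 0.0366% of the reads, at 1.55% in replicate 1 and 1.61% in replicate 2. After Chgb and Chga, tyrosine hydroxylase (Th, the rate-limiting enzyme of catecholamine synthesis) stood at 3205 ± 29.2 CPM and the granule gene Scg2 at 1758 ± 64.6 CPM. None of the 22 genes tested was called, and the median log2 ratio was -0.18 (percentile 12.9), with 15 of the 22 lower in replicate 2. At an adjusted p under 0.05 alone 8 differed, each under 2-fold. Chgb (log2 ratio 0.13) and Chga (0.12) were higher in replicate 2 and the others lower, namely Scg2 (-0.18), the neuropeptide gene Npy (868 and 383 reads, log2 ratio -0.95), Scg5 (-0.90), Pcsk1n (-0.90), Resp18 (-0.83) and the adrenaline-forming enzyme gene Pnmt (-0.52). With the length trend removed, Npy stood at -0.23, Scg5 at -0.56, Resp18 at -0.21, Pnmt at -0.15 and Chgb at 0.014, none of them past the adjusted p. Chga (0.17), Scg2 (-0.26) and Pcsk1n (-0.96) stayed past it. Adjusted over the list alone, 0 were called in this list and in the glomerulosa and fasciculata lists.

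**Figure D1:**
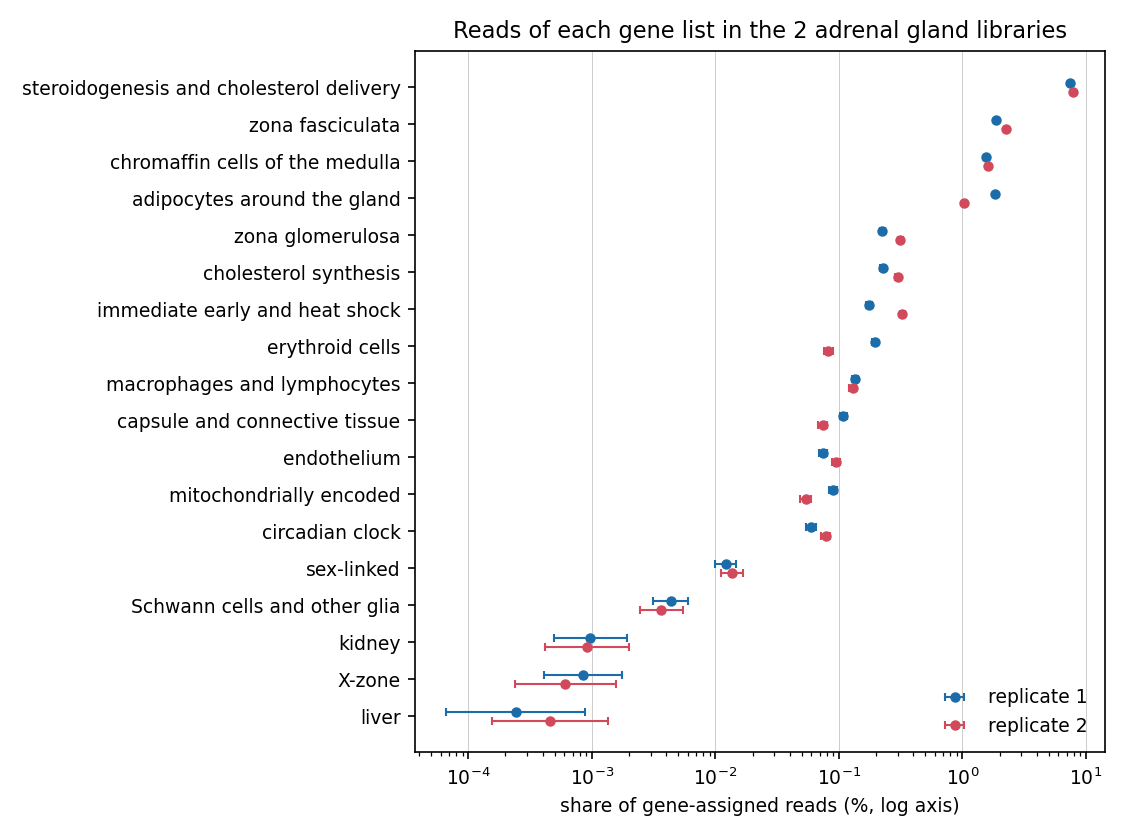
Share of gene-assigned reads (percent, log axis) taken by each fixed gene list in replicate 1 and replicate 2 of the adrenal gland, with Wilson 95% intervals for counting error only. Steroidogenesis genes took 7.49% and 7.86%, and adipocyte genes 1.83% and 1.03%.

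Genes of fat cells and red blood cells differed between the libraries. Adipocyte genes took 1.83% of the reads in replicate 1 and 1.03% in replicate 2, and all 9 tested were lower in replicate 2, with a median log2 ratio of -1.31 at percentile 0 of random lists. Of these, 5 passed the test: Ucp1, the uncoupling protein of brown fat (1268 and 357 reads, log2 ratio -1.60), Fabp4 (-1.56), Cidea (-1.73), Adipoq (-1.33) and Retn (-1.31). Car3 (-0.75) and Cfd (-0.79) stayed under 2-fold. Of the 9 genes, 8 differed at an adjusted p under 0.05 alone. Once the length trend was removed, the list median was -0.75 with 4 called, since Retn moved to -0.75, and Cfd moved to -0.24. Haemoglobin genes were also lower in replicate 2, with 4 of 5 erythroid genes called, among them Hba-a1 (846 and 276 reads, log2 ratio -1.39) and Hbb-bs (450 and 166 reads, -1.21), and a list median of -1.39. After removal of the length trend the median was -0.74 and 1 was called, Hbb-bt (-1.37), while Hba-a1 at -0.74, Hbb-bs at -0.52 and Hba-a2 at -0.68 fell under 2-fold but still passed the adjusted p. Reads can be shared among near-identical haemoglobin copies, so their single values are uncertain.

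Connective tissue genes were lower in replicate 2 by a median log2 ratio of -0.57 (percentile 0.26). Acta2 (-1.18) and Lum (-2.21) were called among 10 tested, while Col3a1 (257 ± 68.7 CPM, -0.65), Dcn (213 ± 81.5 CPM, -0.90), Tagln (118 ± 23.1 CPM) and Col1a1 (97.4 ± 14.99 CPM) were not. The adjusted p alone was passed by 4, Col3a1 and Dcn besides the called ones. No endothelial gene of 9 tested was called (list median 0.02, percentile 56.0), with Plvap at 322 ± 97.4 CPM, Eng at 175 ± 43.2 CPM, Egfl7 at 91.1 ± 16.9 CPM and Pecam1 at 63.8 ± 13.1 CPM. Plvap (0.52) alone passed the adjusted p. No macrophage or lymphocyte gene of 8 tested was called (list median -0.19, percentile 18.0). These were led by the antigen presentation genes Cd74 at 547 ± 7.30 CPM, H2-Ab1 at 257 ± 4.79 CPM and H2-Aa at 81.6 ± 7.32 CPM, with the lysozyme gene Lyz2 at 165 ± 24.3 CPM. Ptprc, Cd3e and Cd79a had 0 reads in both libraries. Adjusted over the list alone, the calls were 5 for adipocytes, 4 for erythroid cells, 2 for connective tissue and 0 for endothelium and for macrophages and lymphocytes.

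Marker genes of neighbouring organs had few reads. The kidney list had 8 and 6 reads, 6 in each library from Aqp2, and the liver list 2 and 3, with Alb at 0 and 1. Glial genes had 36 and 24 reads, mostly from Mbp (16 and 8) and S100b (14 and 9), and 0 of the 2 tested were called (list median -0.56, percentile 15.9). The Y-linked genes Ddx3y (58.4 ± 3.60 CPM) and Eif2s3y (55.9 ± 15.6 CPM) were read in both libraries, Uty had 17 and 4 reads and Kdm5d 0 and 2, and Xist had 0 in both. None of the 3 sex-linked genes tested was called (list median 0.02, percentile 52.8).

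The immediate early and heat shock list had a median log2 ratio of 0.64 over 8 tested genes, at percentile 100 of random lists, with 2 of the 8 called as higher in replicate 2. Nr4a1, a nuclear receptor gene induced by corticotropin, was called at 696 and 1218 reads (log2 ratio 1.03, adjusted p = 8.36e-51, exact binomial test), as was the heat shock gene Hspa1b (39 and 70 reads, 1.06). After the same removal, Nr4a1 stood at 0.95 and Hspa1b at 0.94, each just under 2-fold and still past the adjusted p. Jun (605 ± 233 CPM, 0.70), Junb (205 ± 68.0 CPM, 0.59) and Dusp1 (103 ± 18.3 CPM, 0.26) were not, though Jun and Junb passed the adjusted p alone. Ier2 (85 and 60 reads, -0.27) and Egr1 (16 and 14 reads, 0.03) were not called either, and Fos had 9 and 8 reads, too few to test. Clock genes were not called in 7 tested, with Dbp at 319 ± 80.6 CPM, Tef at 136 ± 48.5 CPM, Nr1d1 at 70.5 ± 22.2 CPM and a list median of 0.28 (percentile 89.2). Dbp (0.42) and Tef (0.64) passed the adjusted p alone, and with the length trend removed the list median was 0.07 and Tef (0.49) no longer passed. Mitochondrially encoded genes took 0.0894% and 0.0539% of the reads, with mt-Co1 at 309 ± 103 CPM and a list median of -0.79 (percentile 0). Of 11 tested, mt-Cytb (-1.19), mt-Nd1 (-1.23) and mt-Nd2 (-1.04) were called as lower in replicate 2, and mt-Co1 (-0.79) passed the adjusted p alone. With the length trend removed the list median was -0.43 and none was called: mt-Cytb stood at -0.82, still past the adjusted p, and mt-Nd1 at -0.71 and mt-Nd2 at -0.59 no longer were. Adjusted over the list alone, 2 immediate early, 0 clock, 0 glial, 0 sex-linked and 3 mitochondrial genes were called.

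Across the transcriptome the libraries were close but differed by more than sampling noise. Both detected 13192 of the 16457 genes seen in either, 12094 of them protein coding and 209 lincRNA genes. Of the 3265 genes seen in only 1 library, 94.2% had at most 3 reads. Log2 CPM correlated across genes with a Pearson r of 0.924 and a Spearman rho of 0.928, where genes are not independent replicates. Chi-square per degree of freedom was 4.01 over 9977 genes, so the libraries are not 1 library deposited again, and the biological coefficient of variation was 0.201. Of 8063 genes tested, 93.4% lay within 2-fold and 264 were called, 184 higher in replicate 1 and 80 higher in replicate 2. At an adjusted p under 0.05 alone, 859 passed. The split depended on scaling: 127 and 119 by library total, and 226 and 58 by DESeq2 size factors.

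The largest ratios included those of pseudogenes and of genes that overlap a neighbour. Higher in replicate 1 were the lincRNA gene AC154200.1 (67 and 0 reads, 19.1-fold), Gm45233 (24 and 0, 6.84-fold), Pcdhga2 (22 and 0, 6.27-fold), Gm6969 (27 and 3), Tbx3os1 (154 and 23), Lum (30 and 5), Cluap1 (18 and 3), Rps27a-ps2 (32 and 6) and Ift43 (22 and 4). Higher in replicate 2 were Mpc1-ps (0 and 57, 22.2-fold), Gm45837 (43 and 284, 7.61-fold), Gm7247 (12 and 72), Gm10774 (6 and 35), Vcp-rs (25 and 119), Fam222a (8 and 34), Gm44597 and Ccdc84 (4 and 17 each) and Elf2 (8 and 31). Lower bounds take the empty library at 3 reads. With the length trend removed, Gm6969 (log2 ratio -2.69 and then -1.91), Cluap1 (-2.13 and -2.07), Rps27a-ps2 (-2.07 and -1.29), Ift43 (-2.06 and -1.45) and Gm44597 (2.11 and 2.04) no longer passed the adjusted p. All of these stayed beyond 2-fold, and Cluap1 hardly moved. Gm44597 had no annotated length and was taken at the median length, so its small move does not bear on the trend. Pseudogenes and overlapping genes can exchange reads with their partners, so these values are uncertain.

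The ratio of the libraries also moved with transcript length. Of 10 bins of genes by length, the one with the shortest transcripts had a median log2 ratio of -0.63 and the one with the longest 0.15, with a Spearman rho of 0.393 across 7897 genes. With this trend removed, which was chosen after seeing the data, 120 genes were called, 75 higher in replicate 1 and 45 higher in replicate 2, of which 96 were among the 264. Adjusted list medians were -0.75 for adipocytes (4 called), -0.74 for erythroid cells (1 called), -0.51 for connective tissue (2 called), -0.43 for mitochondrially encoded genes (0 called), 0.54 for immediate early genes (0 called) 0.22 for cholesterol synthesis (1 called), -0.16 for chromaffin cells (0 called), 0.05 for the fasciculata list and 0.12 for the glomerulosa list (0 called in each). For lists with no call in either case, they were 0.07 for clock genes, -0.09 for endothelium, 0.09 for macrophages and lymphocytes and -0.12 for sex-linked genes. In the steroidogenesis list 12 genes passed the adjusted p alone in place of 14: 5 lost it, Star among them (0.19 and 0.03), and Mrap, Lipe (-0.33 and -0.52) and Soat1 (-0.24 and -0.35) gained it. Fdx1 passed in both cases but turned from -0.21 to 0.34.

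**Figure D2:**
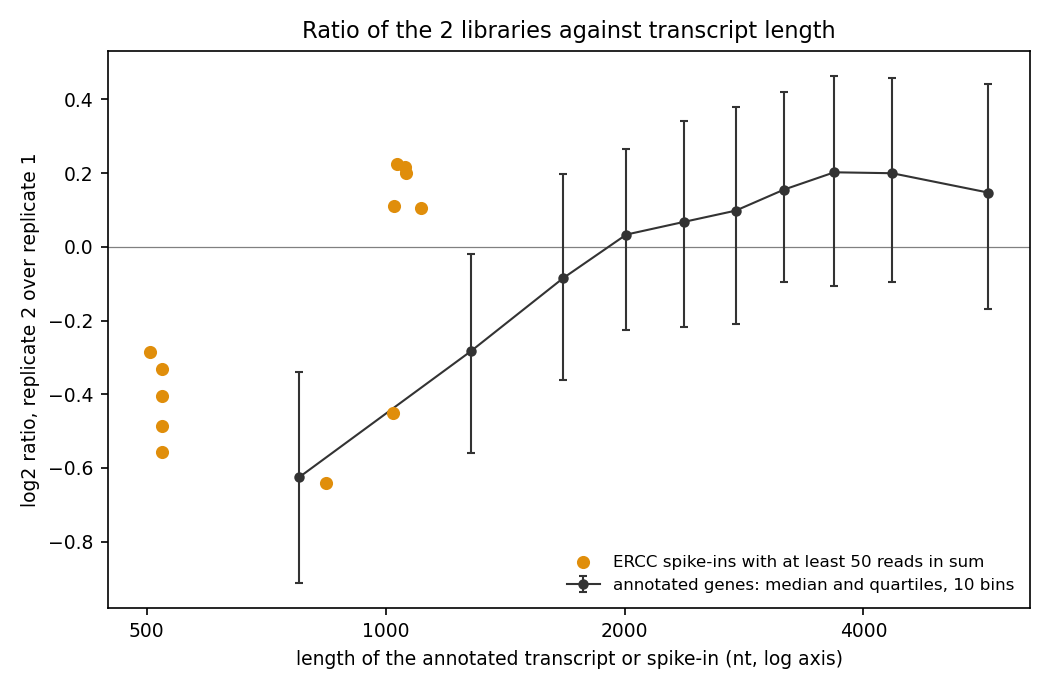
Log2 ratio of replicate 2 over replicate 1 against transcript length (nt, log axis). Black points are medians of 10 bins of annotated genes with bars for the quartiles, on the TMM scale, and orange points are ERCC spike-ins with at least 50 reads in sum, scaled to the spike-in total. The bin of shortest transcripts lies at -0.63 and the highest bin at 0.20.

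Most molecules matched annotated transcripts. Annotated models took 76.9 ± 0.225% of the reads, incomplete splice matches 8.14 ± 0.0520%, new combinations of known splice sites 4.53 ± 0.929% and models with a new splice site 3.67 ± 0.384%. Reads of no compatible splice pattern took 4.67% in replicate 1 and 3.33% in replicate 2, and new combinations 3.88% and 5.19%. Antisense models took 2.33 ± 0.0512% and intergenic models 0.438 ± 0.0416%.

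Most of the fixed steroidogenic genes were read mainly as 1 annotated isoform. Star-201 held 82.5 ± 1.29% of the reads of Star, Cyp21a1-201 86.2 ± 3.08%, Cyp11b1-201 89.1 ± 0.878%, Akr1b7-201 93.3 ± 2.36%, Fdx1-201 92.2 ± 0.624%, Fdxr-201 75.8 ± 0.598%, Mrap-201 83.8 ± 3.28% and Por-201 73.9 ± 5.97%. Cyp11a1 and Hsd3b1 departed from this. Cyp11a1-201 held 53.9 ± 13.4% of the reads of its gene, beside the single-exon reads described above, and 77.4 ± 0.208% of the reads of Hsd3b1 formed an incomplete splice match of 4 exons. Scarb1-201 held 84.8 ± 3.38% and Scarb1-202 2.96 ± 0.223%. In the medulla, Chgb-201 held 92.5 ± 1.35%, Chga-201 86.9 ± 2.81%, Th-201 91.4 ± 1.54%, Pnmt-201 92.4 ± 0.743%, Npy-201 92.0 ± 2.49% and Dbh-201 63.5 ± 2.90%. Gnas, which encodes the stimulatory G protein subunit, was divided among Gnas-208 (47.6 ± 2.90%), Gnas-207 (22.2 ± 2.02%) and Gnas-206 (12.4 ± 0.147%), and the pyruvate kinase gene Pkm between Pkm-201 (71.3 ± 3.61%) and Pkm-202 (19.4 ± 2.37%). The other fixed genes were led by Ldha-202 (95.7 ± 0.126%), Clta-206 (86.5 ± 5.85%), Apoe-206 (76.5 ± 7.40%), Cltb-202 (72.7 ± 8.73%) and Tpm1-211 (38.9 ± 1.92%). The isoform list as a whole took 9.50 ± 0.244% of the reads, with 0 of 28 genes called between the libraries, 0 when adjusted over the list alone and a median log2 ratio of -0.17 (percentile 27.5). Of the 28, 16 differed at an adjusted p under 0.05 alone, and 8 with the length trend removed.

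Of 5330 genes with enough reads, 4016 (75.3%) had no transcript with 90% of the reads, and the median dominant share was 79.2%. The other reads of a gene include incomplete splice matches, single-exon reads and rare new models, so a lower share does not by itself show another major isoform. The dominant transcript was the same in both libraries for 5082 genes (95.3%) and was annotated for 5018. Usage differed in 21 of 5193 genes tested, Cyp11a1 among them, where Cyp11a1-201 held 44.4% of reads in replicate 1 and 63.4% in replicate 2. Apoe-206 differed too, at 71.2% and 81.7%. Single-exon reads of Apoe moved the opposite way, with 448 of its 1787 reads in replicate 1 and 147 of 978 in replicate 2. Those of Cyp11a1 also fell, from 50.3% to 28.3%, so neither call by itself shows a switch between spliced isoforms. The largest differences were for an incomplete splice match of Gm45837 (0% and 78.2%), Rhbdl1-201 (22.6% and 63.8%), an incomplete splice match of Pde2a (36.3% and 76.3%), Rab4b-201 (95.0% and 59.6%) and the cofilin transcript Cfl1-202 (98.6% and 67.6%, adjusted p = 3.06e-23, Fisher's exact test). Gm45837 and Pde2a overlap on the same strand of chromosome 7, so reads assigned to one can belong to the other.

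New spliced transcripts of known genes were numerous, and 77.1% had 1 read in sum. Of 54247 in either library, 8177 were in both and 912 had at least 5 reads in each, 656 of them new combinations and 256 with a new splice site, in 671 genes. The most abundant was a transcript of Srd5a2 (ENSMUSG00000038541.8), the steroid 5α-reductase gene, with 1661 and 1760 reads (44.7% and 47.9% of the gene). It differs from Srd5a2-201 by an additional intron of 59 nt in the 3′ UTR (chromosome 17, 74017151 to 74017209, mm10). In the antizyme genes Oaz1 (1285 and 891 reads) and Oaz2 (179 and 197 reads), the reads ran through an annotated gap of 4 nt in the coding region, at 80828292 to 80828295 on chromosome 10 and 65686269 to 65686272 on chromosome 9. These models were the main form of each gene, with 95.6% and 94.4% of the reads of Oaz1 and 82.9% and 90.4% of Oaz2. All their introns are annotated, so they are new only in lacking that gap and show no new splice junction.

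The remaining abundant new transcripts differed from the annotation mainly by short exons or shifted splice sites. Reads lacked the 12 nt exon 3 of Idh3g (258 and 166 reads), the 20 nt exon 2 of Chmp1a (177 and 207), the 16 nt exon 13 of Hnrnpk (193 and 168) and the 6 nt exon 9 of Phb2 (167 and 138). Mknk2 (242 and 237 reads) used another donor 42 nt away in the 5′ UTR, and Ctbp1 (197 and 170) an acceptor 3 nt away. Cyb561 (204 and 185) had its first donor 4011 nt away, also in the 5′ UTR. Its model starts at 105940164 on the minus strand of chromosome 11, so the donor of Cyb561-201 at 105944111 lies outside it. The Cyb561 model thus has another first exon, not a donor shifted within the same exon. Over all annotated internal exons with enough reads, 75 of 77 exons of 3 to 15 nt were held by under 5% of the reads, as were 102 of 325 exons of 16 to 30 nt, against 1310 of 34218 exons of 51 to 200 nt. The classes also differ in annotation. Exons that no annotated transcript of the gene skips were 8 of the 77, 169 of the 325 and 28550 of the 34218.

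**Figure D3:**
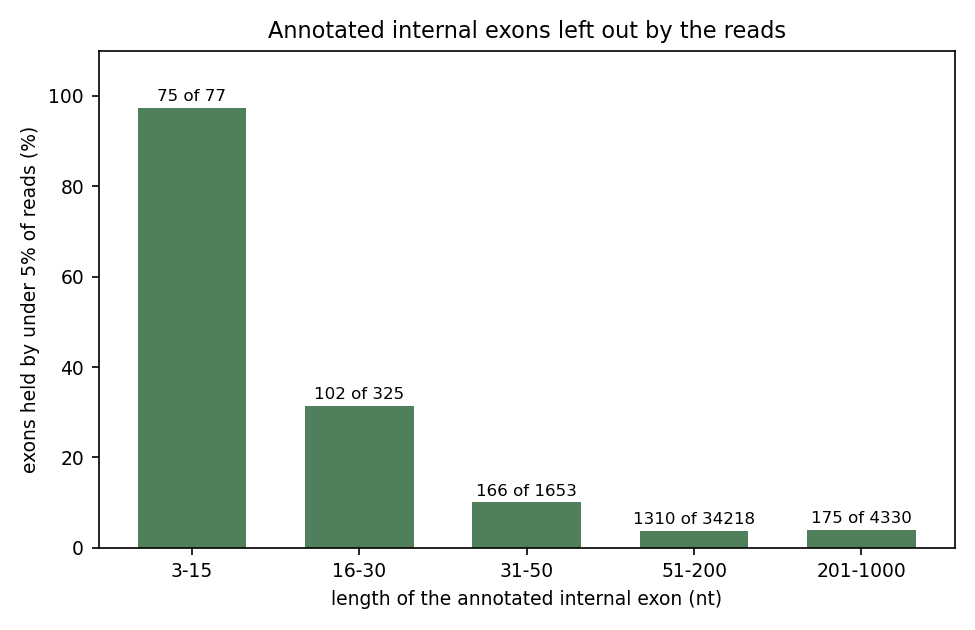
Percent of annotated internal exons held by under 5% of the reads that hold or skip them, by exon length in nt, over both libraries. Bars start at 0 and carry the counts, from 75 of 77 exons of 3 to 15 nt to 175 of 4330 exons of 201 to 1000 nt. The length classes also differ in the share of exons that an annotated transcript skips.

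Outside annotated genes, 14044 new loci were seen in either library, of which 376 had at least 5 reads in each. Of these, 328 were antisense and 301 had a single exon. Abundant ones lay opposite Gm26917 (215 and 801 reads), Actb (627 and 264), CT010467.1 (258 and 161) and Kcnk3 (254 and 129). The locus opposite Actb spans 142901895 to 142903654 on chromosome 5 and that opposite Kcnk3 30621896 to 30624017 on the same chromosome (mm10). How strand was set is not given in the sources used here, so reads of these loci and of their partner genes may not be separable.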

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

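All tests in this part were chosen after the result was seen. Spike-in reads, which enter none of the gene comparisons, drew attention because they changed with length between the libraries: molecules under 600 nt had 1870 reads in replicate 1 and 1308 in replicate 2, against 3700 and 3737 for those of 900 to 1200 nt. The odds ratio of 0.693 (95% interval 0.637 to 0.753, Fisher's exact test p = 7.88e-18) compares these libraries only and covers counting error only, and spike-ins differed among themselves, with ERCC-00108 of 1022 nt (41 and 27 reads, log2 ratio -0.45) and ERCC-00113 of 840 nt, outside both classes (130 and 75 reads, -0.64), as low as the short ones. Over single spike-ins with at least 50 reads, the 5 short ones had a mean log2 ratio of -0.41 and the 6 long ones 0.07 (two-sided exact permutation test, p = 0.0173), and without length classes the Spearman rho of ratio and length was 0.589 over all 12 (permutation p = 0.0476), but both tests repeat the observation that drew attention, so gene expression alone stays open as the source of the length trend among genes, where medians were -0.79 at 500 to 600 nt and -0.37 just above 1000 nt. Reads matching only the 3′ part of an annotated splice chain differed by 0.0270 percentage points, but pieces inside the last exon are read as a single exon, and single-exon reads took 11.8% in replicate 1 and 9.79% in replicate 2, so RNA broken at its 5′ side in replicate 1 stays open. A lower recovery of short molecules in the preparation of replicate 2 may account for the trend and stays open too, since the only values that bear on it are those of the same spike-ins.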

How the results depend on the processing

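Removal of the length trend and restriction to genes that overlap no other were added after the data were seen, and the other alternatives reported here were chosen before the data were examined. Of 341 values of log2 ratios for 37 named genes, 312 kept their direction and side of the threshold, 27 fell short of it and 2 turned. Values exist only where a gene was still tested, so genes that overlap another have none under the restriction to genes that overlap no other. Of 104 values for list shifts, 99 kept their place inside or outside the central range of random lists, but not always their direction. Inside that range, the steroidogenesis median turned from -0.11 to 0.05 with annotated transcripts. The median for macrophages and lymphocytes turned from -0.19 to 0.09 with the length trend removed. Of 11 counts of genes that differ, 10 lay within 1.5 times of 264. Of 355 mean levels of 73 named genes, 309 moved by less than 1 SD. Among these are the cases with 1 library left out, where a mean of 2 moves by less than 1 SD by construction. Where no cause is named, the cause was not tested.

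The correlation of 0.924 moved to 0.788 with 0.1 CPM added, 0.967 with 10 CPM, 0.927 at 20 reads in sum, 0.914 with annotated transcripts and 0.916 with the deeper library thinned. Calls numbered 120 with the length trend removed. The log2 ratio of Cyp11a1 turned from -0.51 to 0.0075 without reads of no compatible splice pattern and to 0.024 with annotated transcripts. These leave out the single-exon reads of the gene. The cholesterol synthesis shift of 0.24 passed the central 95% of random lists at 50 reads in sum (0.29), with spliced (0.23) or annotated transcripts (0.32) and with the length trend removed (0.22). With spliced transcripts the immediate early shift was 0.21 and no longer passed, since genes read as a single exon drop out.

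With mitochondrial and the 10 most abundant genes out of the total, shares became 8.46% for steroidogenesis, 1.74% for chromaffin cells, 0.146% for macrophages and lymphocytes, 0.00104% for kidney, 0.0142% for sex-linked genes and 10.5% for the isoform list. A smaller total raises each share by construction. Without reads of no compatible splice pattern, they were 6.81% for steroidogenesis, 0.000397% for the X-zone, 1.62% for chromaffin cells, 0.136% for macrophages and lymphocytes and 8.70% for the isoform list. With spliced transcripts, they were 7.25% for steroidogenesis, 0.000428% for the X-zone, 1.74% for chromaffin cells, 0.145% for macrophages and lymphocytes, 0.000988% for kidney, 0% for mitochondrially encoded genes, which have a single exon, and 0.0144% for sex-linked genes. With annotated transcripts, they were 6.64% for steroidogenesis, 2.38% for the zona fasciculata, 0.000414% for the X-zone, 1.79% for chromaffin cells, 0.158% for macrophages and lymphocytes, 0.00992% for sex-linked genes and 8.84% for the isoform list.

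Among spliced reads, annotated models took 82.7%, incomplete matches 7.86%, new splice sites 4.11%, no compatible pattern 0.0870%, antisense 0.109% and intergenic 0.0532%. New spliced transcripts numbered 8177 at 1 read and 389 at 10 reads in each library. Genes that differed in usage numbered 34 with incomplete splice matches left out and 11 at 20 percentage points. Genes with no transcript at the threshold numbered 1804 at 50 reads in each library and 2292 at 75%. These counts follow from the thresholds, except the 34. Ratios between the libraries have no value without one of them, and the X-zone, kidney and liver lists had no gene with enough reads for a shift. Depth limits single genes: in simulation with sampling noise only, 68% of 3-fold changes were called, and 100% among genes with at least 100 reads in sum.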

Other observations

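The second fat-cell list, the tests on exons that no annotated transcript skips, on spanning reads of short introns and on overlapping genes, and the removal of the length trend were chosen after the results that led to them were seen. Further genes of fat metabolism were abundant in these glands. Gpd1 stood at 2029 ± 257 CPM (n = 2), the lipid droplet gene Cidec at 1374 ± 201 CPM, Thrsp at 861 ± 230 CPM, Cox8b, a respiratory chain subunit gene of brown fat and muscle, at 783 ± 575 CPM and Pck1 at 553 ± 127 CPM. Cox8b had 980 reads in replicate 1 and 247 in replicate 2 (log2 ratio -1.76), Cox7a1 222 and 63 (-1.58), Aqp7 61 and 16 (-1.66) and Cpt1b 175 and 62 (-1.26). Of the 18 tested genes of this list, which shares no gene with the first, 17 were lower in replicate 2 and 5 were called. With the length trend removed 3 were called, Aqp7 (-1.72), Cpt1b (-1.35) and Cd36 (-0.94 before and -1.11 after), while Cox8b (-0.98) and Cox7a1 (-0.80) lay under 2-fold and Orm1 (27 and 7 reads, -1.63 and then -1.02) no longer passed the adjusted p.

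Fat-cell genes were lower in replicate 2. With the length trend removed, the fixed adipocyte list kept a median log2 ratio of -0.75, below the central 95% of random lists (-0.35 to 0.17), which argues against the trend as the whole cause. Calls went from 5 to 4, since Retn moved from -1.31 to -0.75, under 2-fold. The second list stood at -0.64 against -0.22 to 0.16, in line with more attached fat tissue in replicate 1, and Car3 and Cfd were the most abundant genes of the first list, at mean levels of 7081 and 3432 CPM. How many of these genes the gland itself expresses was not measured here, and a difference in fat cells between animals was not tested and stays open.

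Most of the 10 most abundant new transcripts differ from the annotation by short segments, with Cyb561 and its donor 4011 nt away as an exception. Median inclusion was 0% for the 77 annotated exons of 3 to 15 nt, 97.0% for the 325 of 16 to 30 nt and 100% for those of 51 to 200 nt. Short exons passed over in alignment are thus a candidate explanation for Idh3g and Phb2. For Hnrnpk and Chmp1a, with exons of 16 and 20 nt, the class median cannot decide. Of the 325 exons in their class 102 were under 5%, and these exons stood at 0% and 3.91%. Skipping in the tissue stays open, since the exons of 3 to 15 nt that no annotated transcript of the gene skips also had a median inclusion of 0% but are only 8 of the 77 and leave out Idh3g and Phb2. Of 169 such exons of 16 to 30 nt 9 were under 5%, Hnrnpk and Chmp1a among them, against 0 of 1209 such exons of 31 to 50 nt. Of 8 unannotated introns under 70 nt inside exons, 7 held 30 to 70% of spanning reads, against 20 of 67 longer ones (Fisher's exact test p = 0.00266), and Srd5a2 held 51.7% and 54.9%. Such shares could come from a deletion on the CAST allele, but 75% of the 8 have GT and AG ends, as introns do, so deletions and introns cannot be told apart here without allele sequences.

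Among the 28 genes called at 4-fold or more, 14 overlap another annotated gene on the same strand, against 22.4% of 7799 tested genes that were not called (odds ratio 3.47, Fisher's exact test p = 0.00205), while over all 264 called genes the share was 23.1%. Usp50, itself just under 4-fold (log2 ratio -1.98), had 155 and 33 reads where Gm10774, which it overlaps, had 6 and 35. Summed, the pair had 161 and 68 reads (log2 ratio -1.02), so reads exchanged between these genes alone do not account for the whole fall of Usp50.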
